A study of Mus musculus with 36 samples.

How the data were processed

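Polyadenylated RNA was sequenced from 12 mouse livers and 24 cultures of mouse embryonic fibroblasts (MEFs), in 4 and 8 groups of 3 libraries. For liver, the deposited values were raw counts per gene, made with HISAT2 and Subread on build mm10 per the submitters' processing notes, which also list DESeq2 and edgeR. For MEFs, the deposited values were on a log2 scale after a variance-stabilizing transformation that normalized the 24 libraries together, and STAR 2.7.10b, featureCounts, DESeq2 and limma are listed per the submitters' processing notes. Versions of the other tools, strand settings and filters were not stated. Groups were taken from the column names as they spell out the labels. Liver columns show the group but no replicate number, so the libraries of a group are called a, b and c. MEF columns are headed GFP (labelled wild type) or CRE (labelled Vps15 knockout), with numbers 1 to 3. Whether replicates were separate animals or cultures is known only as far as the labels say, and p-values measure the spread between the samples. Between replicate libraries the chi-square of counts per degree of freedom, 1 for counting error alone, was 7.4 to 16.7 in liver. In MEFs it was 1.89 to 5.14, except 18 and 20 for pairs with CRE library 3 at 4 h of replenishment. The MEF p-values thus rest on a small spread between replicates. The number of columns not used was 0.

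Liver values covered 136300 genes, 87774 of them with NONCODE identifiers, which took 20.5 to 24.8% of counts per library. Of 48526 Ensembl identifiers 48058 matched a symbol in the GENCODE M21 annotation (GRCm38, the mm10 build), from which coordinates were taken. All 32266 MEF symbols matched a RefSeq gene name. Liver totals were 9110836 to 12870944 counts. Undoing the transformation of the MEF values gave whole counts (within 0.01) in 100% of cases, summing to 19345029 to 21245006 per library. These counts were used only for depth and for alternatives.

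Liver counts were filtered with filterByExpr (23875 genes left), scaled by trimmed mean of M-values (TMM; factors 0.801 to 1.22) and tested with edgeR's quasi-likelihood F test, with 1 mean per group over the 12 libraries. Standard errors of edgeR changes are the absolute log2 change divided by the square root of F. The MEF test was planned as edgeR if whole counts were held and limma on the log2 values otherwise. The deposited log2 values were therefore tested with limma, with a mean-variance trend and robust moderation, over the 24 libraries, for the 13914 genes whose mean was at least 1 above the lowest value of 4.17. Comparisons, 5 in liver and 13 in MEFs, were fasting or medium within each label, label within each condition, and their interactions. P-values were adjusted by Benjamini and Hochberg over all tested genes, with a threshold of 0.05. Of the gene lists written beforehand, 40 in liver and 30 in MEFs had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Folds against a group with 0 counts are lower bounds at a floor of 3 counts per library, which covers counting error only.

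Genes were named by a rule. It took Pik3r4, Ppara, Fgf21, Mat2a, Atf4, Nr1d1 and Sqstm1 whatever their p, and up to 4 members with the smallest adjusted p of each list described. It also took the 8 largest rises and the 8 largest falls among genes past 0.05 whose libraries did not overlap between the groups (a condition left out for interactions). The higher group of these had to reach 5 CPM, or the median of tested genes for log2 values. Symbols of the form Gm plus digits, those ending in Rik and genes without a symbol were left out. Fgf21 was not among the tested MEF genes. Not every gene so selected is printed. The mitochondrial genes ND1, ND2 and ND3 are printed per library and were chosen after their values were seen. The design, this rule, the lists and the alternatives were fixed before the data were examined, except where said otherwise. The replicate number as a block, planned for liver too, could not be run there.

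Alternatives were DESeq2, RLE factors, no filter, only the compared groups, and each library left out in turn for liver; and a shift of each library to 1 median, no filter, no trend, the replicate number as a block, only the compared groups and each library left out in turn for MEFs. Chosen after the data were seen were Ensembl genes only and library sizes alone for liver, and edgeR and DESeq2 on the recovered counts for MEFs. Up to 33 splits of the same libraries were refitted per comparison.

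The steps were tested on simulated data. For fasting in wild-type liver, edgeR on 22136 genes called 33 of 100 genes changed by a log2 of 1 and 98 of 100 changed by 2, with 6 false calls, and DESeq2 on 21277 genes called 38 and 95, with 10 false calls. For CRE against GFP in basal MEFs, limma on 13914 genes called 100 of 100 at each size, with 16 false calls. In comparisons simulated with no change the number of calls was 0. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, data.table version 1.17.8, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.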

Results

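The series measured polyadenylated RNA by sequencing in mouse liver and in mouse embryonic fibroblasts (MEFs), each with and without Vps15, the regulatory subunit of the class 3 phosphoinositide 3-kinase, which the gene Pik3r4 encodes. The liver set held 12 libraries in 4 groups of 3, from 4-week-old males killed at zeitgeber time 14. The groups were wild-type and hepatocyte-specific knockout livers, fed or fasted for 24 h. The MEF set held 24 libraries in 8 groups of 3. These cells carried floxed Vps15 alleles and received an adenovirus with GFP or with CRE, and were kept in basal medium, deprived of methionine for 4 h, or deprived for 4 h and then given methionine back for 1 h or 4 h. The liver libraries held 9110836 to 12870944 counts each. The whole counts recovered from the deposited MEF values summed to 19345029 to 21245006 per library.

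Pik3r4 (ENSMUSG00000032571, chromosome 9, 105642978 to 105687657, plus strand, mm10) was read first because it is the gene the labels name. In liver it stood at 21.2 ± 3.14 CPM (counts scaled to library size by TMM; mean ± SD, n = 3 here and in each liver group below) in fed wild-type, 22.3 ± 2.07 in fasted wild-type, 24.0 ± 1.63 in fed knockout and 21.1 ± 2.87 in fasted knockout libraries. The knockout to wild-type log2 fold change was 0.18 ± 0.14 (SE) in fed liver and −0.08 ± 0.14 in fasted liver (edgeR quasi-likelihood adjusted p = 0.315 and 0.666). With library sizes alone these became 0.56 and 0.44, past 0.05. The labels do not give the deleted part, and a total over the whole gene does not check a deletion that leaves the rest transcribed, so these livers are called labelled knockout here. In MEFs the deposited log2 value of Pik3r4 was higher in columns headed CRE than in columns headed GFP in basal cells, 10.1 ± 0.02 against 9.91 ± 0.11 (limma adjusted p = 0.000332). It was also higher in deprived cells (log2 difference 0.22, adjusted p = 0.000557) and after 1 h of replenishment (0.15, adjusted p = 0.0163), and it differed by 0.05 at 4 h (adjusted p = 0.414). The difference at 1 h missed the threshold without GFP library 1 (0.12) or without CRE library 3 (0.13). From basal to deprived cells Pik3r4 fell under both headings (log2 difference −0.265 under GFP and −0.278 under CRE). It fell as well from 1 h to 4 h of replenishment (−0.172 and −0.269). The same limit holds for these totals, so they do not check the headings, and MEF groups are named by heading throughout.

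Fasted and fed wild-type livers were compared to ask which transcripts respond to 24 h without food. Fatty acid oxidation and ketogenesis genes that are targets of the receptor PPARα were higher in fasted liver: 46 of 56 rose and 2 fell, with a median log2 fold change of 1.03 and the same counts adjusted over the list alone. Cyp4a14, a microsomal fatty acid hydroxylase, rose from 206 ± 10.6 to 5096 ± 96.6 CPM (log2 fold change 4.63 ± 0.67 SE, adjusted p = 0.00119). Cidec, a lipid droplet protein, rose by 4.26 ± 0.24, Angptl4 by 2.79, the droplet coat gene Plin2 by 1.65 and Hadhb of mitochondrial β-oxidation by 1.38. Of 41 genes of gluconeogenesis, amino acid catabolism and fasting transcription, 22 rose and 0 fell (27 and 0 adjusted over the list alone; median 0.73), among them Lpin2 (2.62), the amino acid carrier Slc7a2 (2.04) and pyruvate carboxylase Pcx (0.97). Of 74 nuclear genes of oxidative phosphorylation, 41 rose (48 adjusted over the list alone; median 0.35), and 7 of 18 hepatocyte markers rose with them (median 0.24). Ppara itself rose from 71.3 ± 9.31 to 121 ± 21.7 CPM and the hepatic hormone Fgf21 (chromosome 7, 45613886 to 45615490, minus strand) from 5.26 ± 3.45 to 54.5 ± 4.91 CPM. Sqstm1, an autophagy receptor, rose by 1.12 ± 0.12 and the S-adenosylmethionine synthetase gene Mat2a by 0.52 ± 0.13, a call lost with library sizes alone (0.33, adjusted p = 0.0587). Atf4 differed by −0.07 (adjusted p = 0.788) and the clock repressor Nr1d1 by 1.35 (adjusted p = 0.0968, and 0.0474 at a change of 0.90 without fed library b).

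Lipid-synthesis and immune transcripts were lower in the same livers. The lipogenic regulator Srebf1 was at −3.48 on the log2 scale, fatty acid synthase Fasn at −2.27 and Thrsp at −3.04. Of the genes of fatty acid synthesis and glycolysis 17 of 34 fell while 6 rose (the same adjusted over the list alone; median −0.37). Of 29 cholesterol synthesis genes 23 fell and 1 rose (23 and 2 adjusted over the list alone), with Mvd at −2.94 and Sqle at −2.31. Of 24 unfolded protein response genes 20 fell (20 adjusted over the list alone; median −0.83), among them Sdf2l1 (−2.47) and Hyou1 (−1.39). Macrophage and Kupffer cell markers fell in 19 of 20 cases (20 adjusted over the list alone; median −1.48), including Lyz2, Ctss, C1qa and Cd68. So did 8 of 11 neutrophil markers (10 adjusted over the list alone). Of 43 interferon-stimulated genes 29 fell (35 adjusted over the list alone; median −1.25). So did 23 of 49 cell cycle genes (28; median −1.33, or −1.28 with genes at 0 placed at their bound) and 22 of 38 extracellular matrix genes (26 fell and 2 rose adjusted over the list alone), where Col1a1 fell by 2.88 and Col3a1 by 2.58.

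Among single genes the largest rise was that of Ppp1r3g, a glycogen-targeting phosphatase subunit, which had 0 counts in fed wild-type libraries and 50.4 ± 8.96 CPM in fasted ones, at least 160-fold higher. The 8 largest also held Cyp4a14 and Cidec, given above, and Cyp4a12b (5.59), Elovl3 (4.58) and Lamb3 (4.18 ± 0.29). Cyp4a12b belongs to a gene family whose copies share reads, so its value is uncertain. Among the 8 largest falls past an adjusted p of 0.05, Oxtr went from 14.9 ± 10.4 and Greb1 from 6.69 ± 3.82 CPM to 0 counts. In such families, Cyp3a44 went from 135 ± 109 to 0.04 ± 0.07 CPM and Sult3a1 from 339 ± 264 to 0.13 ± 0.14 CPM. The fed libraries differed widely in these genes, and the mean log2 CPM of 19 female-biased liver genes was 4.38 in fed library a against 5.73 and 5.84 in b and c. In all, 6282 of 23875 genes were past an adjusted p of 0.05 in edgeR's quasi-likelihood test, 2981 higher and 3301 lower. With library sizes alone, which moved the median of all genes by −0.19, 1785 were higher and 5202 lower. By camera with a preset correlation these 12 lists had adjusted p between 3.07e-21 and 0.00724, and with an estimated correlation their adjusted p lay between 0.254 and 0.599, so none held in that test.

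In livers labelled knockout, the same comparison of fasting with feeding gave 362 genes past 0.05, 199 higher and 163 lower. Pdk4, a kinase that limits glucose oxidation on fasting, rose from 47.3 ± 21.4 to 165 ± 3.6 CPM (log2 fold change 1.81 ± 0.31, adjusted p = 0.0258). Of the 56 fatty acid oxidation genes 7 rose (16 rose and 1 fell adjusted over the list alone; median 0.27), among them Cidea (2.59), the peroxisomal thiolase Acaa1b (1.03), Creb3l3 (0.75) and Plin2 (0.74). Among the 8 largest rises the tight junction gene Cldn4 rose by 2.26 ± 0.34 on the log2 scale, Fosl1 of the AP-1 family from 25.7 ± 7.4 to 88.8 ± 27.3 CPM, and Krt20, Sphk1, Runx1, Krt23 and Hmga1 rose by 1.70 to 2.80. Fosl1, Dusp5 (1.33), Klf4 (1.36) and Ccn1 (0.63) were among 5 of 37 immediate early genes that rose (6 adjusted over the list alone).

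Among the 8 largest falls in these livers the urea cycle gene Cps1 fell from 572 ± 227 to 236 ± 59.5 CPM, Nnmt by 1.46 and Aldh1b1 by 1.65 on the log2 scale. Of 41 gluconeogenesis and amino acid catabolism genes 3 fell, including the aminotransferase Tat (−0.81), while Sdsl rose by 0.78 (12 and 1 adjusted over the list alone; median −0.30). Of 49 cell cycle genes 5 fell (32 adjusted over the list alone; median −0.82), such as Birc5 (−1.55) and Prc1 (−1.51). Of 20 macrophage markers Ccr2 (−1.21) and Ptprc (−0.76) fell while Cd68 rose (0.62; 10 fell and 1 rose adjusted over the list alone; median −0.39). By camera these 5 lists had adjusted p between 1.99e-13 and 0.0111 with a preset correlation and adjusted p = 0.613 each with an estimated one. Ppara (0.17, adjusted p = 0.652), Fgf21 (0.85, 0.41), Sqstm1 (0.33, 0.134), Mat2a (0.08, 0.813), Atf4 (0.60, 0.0615), Nr1d1 (1.10, 0.316) and Pik3r4 (−0.19, 0.524) were not past 0.05. Atf4 passed it by DESeq2 (0.60), without the filter (0.63), with Ensembl genes alone (0.62) and without fasted library b (0.78), and Nr1d1 in a fit of these libraries alone (1.11). Single libraries decided this count. It was 7 without fasted library a or without fasted library c, 57 without fed library a, 45 without fed library c, 441 without fed library b and 1330 without fasted library b. Of 33 named genes past 0.05, 32, 31, 23, 28, 11 and 0 lost the call in these fits. DESeq2 gave 937 genes, no count filter 1456, Ensembl genes alone 563, a fit of these 6 libraries alone 33, and library sizes alone 165 higher and 302 lower.

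Livers labelled knockout were set against wild-type livers in the fed state to ask what loss of Vps15 does without a fast. Hepatocyte markers were lower in the livers labelled knockout, 17 of 18 (17 adjusted over the list alone; median −1.22), including Cyp2e1 (−2.99), Apoa2 (−1.39), prothrombin F2 (−1.22) and Ttr (−1.31). Oxidative phosphorylation transcripts were lower in 72 of 74 nuclear genes (72 adjusted over the list alone; median −0.74), such as Ndufb11 (−1.15) and Atp5g1 (−1.27). So were 14 of 15 mitochondrially encoded ones (14 adjusted over the list alone; median −1.08). Of 18 bile acid genes 13 were lower and 1 higher (13 and 1 adjusted over the list alone; median −2.38), with Slc27a5 at −2.37, Baat at −2.38 and the bile acid receptor Nr1h4 at −1.54. Unfolded protein response and endoplasmic reticulum chaperone genes were lower, 22 of 24 (22 adjusted over the list alone; median −1.32), with Hspa5 at −1.94 and Hyou1 at −2.33. Of 56 fatty acid oxidation genes 34 were lower and 9 higher (34 and 9 adjusted over the list alone; median −0.52): Fabp1 was lower by a log2 change of −2.78 and Acaa2 by −1.56, while Cidec was higher (4.89).

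Other lists were higher in the same livers. Sqstm1 (chromosome 11, 50199366 to 50210827, minus strand) stood at 804 ± 60.2 against 280 ± 26 CPM (log2 fold change 1.52 ± 0.12, adjusted p = 1.94e-08), and 36 of 61 autophagy and lysosome genes were higher with it and 5 lower (37 and 5 adjusted over the list alone; median 0.45). NRF2 targets were higher in 27 of 37 cases and lower in 4 (29 and 4 adjusted over the list alone; median 0.99), among them the cystine carrier Slc7a11 (8.88), Cbr3 (6.57) and Srxn1 (4.67). Of 40 genes of the amino acid stress response driven by ATF4, 24 were higher and 5 lower (24 and 6 adjusted over the list alone; median 1.26), with Eif4ebp1 at 2.18 and Aldh18a1 at 2.12 and Herpud1 lower (−1.77), whereas Atf4 itself was lower (−0.61 ± 0.16, adjusted p = 0.00418). p53 targets were higher in 22 of 30 cases and lower in 2 (24 and 3; median 1.28), among them the death receptor Tnfrsf10b (5.08) and Bax (1.50). Cell cycle genes were higher in 35 of 49 and lower in 2 (37 and 4; median 1.58), among them Foxm1 (2.50) and Plk1 (2.95). Macrophage markers were higher in 18 of 20 cases (18; median 0.72), with Trem2 at 3.30 and Cd68 at 2.15. Interferon-stimulated genes were higher in 32 of 43 (32; median 1.18), stellate cell markers in 11 of 17 (11 higher and 1 lower; median 0.64) and extracellular matrix genes in 32 of 38 and lower in 1 (32 and 1; median 1.19, or 1.10 with genes at 0 at their bound). The second count or pair in these parentheses was adjusted over the list alone. Of 14 endothelial markers 4 were higher, among them Lyve1 (1.13), and 4 lower, among them Kdr (−0.90; 4 and 4 adjusted over the list alone; median −0.14, camera adjusted p = 0.675, and 0.926 with an estimated correlation).

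Bex2, Krt5 and Ppp1r3g had 0 counts in fed wild-type libraries and stood at 10.5 ± 2.67, 5.44 ± 2.43 and 6.65 ± 3.57 CPM in fed libraries labelled knockout, at least 33.3, 17.3 and 21.1-fold higher. Carbonic anhydrase Car3 went from 1256 ± 429 to 4.38 ± 1.78 CPM and the organic anion carrier Slc22a7 from 53.9 ± 28.7 to 0.47 ± 0.35 CPM. Ppara was lower (−0.51 ± 0.17, adjusted p = 0.024) and Fgf21 higher (1.89 ± 0.56, adjusted p = 0.0224), but both calls were lost in other fits: for Ppara without fed wild-type library a (−0.40) or c (−0.52) or fed knockout library a (−0.46) or c (−0.48), for Fgf21 without fed wild-type library b (1.92) or fed knockout library c (1.40), without the filter (1.88) or in a fit of these libraries alone (1.90). Mat2a (0.24, adjusted p = 0.147) and Nr1d1 (−0.21, adjusted p = 0.772) were not past 0.05. In all, 11022 genes were past 0.05 in edgeR's test, 5572 higher and 5450 lower. With library sizes alone, which moved the median of all genes by 0.37, 9925 were higher and 3055 lower, Atf4 (−0.24) and Ppara (−0.13) lost their calls, and Mat2a (0.61) and Pik3r4 (0.56) passed 0.05. The libraries labelled knockout held 2.01 to 2.65% mitochondrial counts against 3.29 to 3.65% in wild-type libraries, and their 10 highest genes held 4.86 to 6.33% of counts against 7.69 to 8.42%. The 15 of these lists that camera called with a preset correlation had adjusted p between 2.42e-18 and 0.00303, and between 0.217 and 0.406 with an estimated correlation.

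The same contrast was made in fasted liver. Fatty acid oxidation genes were lower in livers labelled knockout in 46 of 56 cases and higher in 7 (46 and 7 adjusted over the list alone; median −1.42), with Acaa2 at −1.96. Of 41 gluconeogenesis and amino acid catabolism genes 31 were lower and 3 higher (31 and 3; median −1.56), with histidase Hal at −4.44. Oxidative phosphorylation genes were lower in 73 of 74 cases (73; median −1.11). Hepatocyte markers were lower in 18 of 18 (18; median −1.38) and bile acid genes in 17 of 18, with 1 higher (17 and 1; median −2.61). Cyp8b1 went from 1546 ± 129 to 3.78 ± 2.62 CPM and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, from 49.4 ± 20.7 to 0.19 ± 0.19 CPM. Ppara stood at 56.5 ± 14.8 against 121 ± 21.7 CPM (−1.10 ± 0.17, adjusted p = 5.3e-05). The second count or pair in these parentheses was adjusted over the list alone.

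Interferon-stimulated genes were higher in fasted livers labelled knockout in 41 of 43 cases (42 adjusted over the list alone; median 2.83), among them Irf7 (2.83), Lgals3bp (1.71) and Bst2 (1.86). Macrophage markers were higher in 20 of 20 (20 adjusted over the list alone; median 1.72), with Cd68 at 4.33. Neutrophil markers were higher in 9 of 11 (9; median 3.85, or 3.46 with genes at 0 at their bound), with S100a9 at 4.38. Cell cycle genes were higher in 37 of 49 and lower in 3 (38 and 4 adjusted over the list alone; median 2.38, or 2.32 at the bound), extracellular matrix genes in 34 of 38 and lower in 1 (35 and 1; median 2.05). NRF2 targets were higher in 25 of 37 and lower in 5 (25 and 5; median 1.10) and amino acid stress response genes in 25 of 40 and lower in 9 (26 and 9; median 1.71). Of the 14 endothelial markers 5 were higher and 3 lower (5 and 3 adjusted over the list alone; median −0.05, camera adjusted p = 0.879, and 0.968 with an estimated correlation). Sprr1a, a squamous differentiation gene, stood at 188 ± 59.1 against 0.27 ± 0.24 CPM and Fosl1 at 88.8 ± 27.3 against 0.08 ± 0.07 CPM. The chemokine Ccl7, the glutathione peroxidase Gpx2, F13a1 and Krt20 had 0 counts in fasted wild-type libraries and were at least 38.9, 23.2, 20.6 and 18.7-fold higher. Sqstm1 was higher by 0.73 ± 0.12 (adjusted p = 3.49e-05), while Fgf21 (−0.64, adjusted p = 0.287), Mat2a (−0.21, 0.189), Atf4 (0.06, 0.771) and Nr1d1 (−0.46, 0.474) were not past 0.05. In all, 13383 genes were past 0.05 by edgeR's quasi-likelihood test, 6686 higher and 6697 lower. With library sizes alone, which moved the median of all genes by 0.51, 11706 were higher and 3567 lower, and Mat2a (0.30), Pik3r4 (0.44) and Nr1d1 (0.05) turned direction, the first 2 past 0.05, and Atf4 (0.57) passed it. Without fasted wild-type library c, Mat2a (−0.32) passed it too. The 12 lists that camera called with a preset correlation had adjusted p between 1.83e-20 and 0.000653, and between 0.229 and 0.24 with an estimated one.

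**Figure D1:**
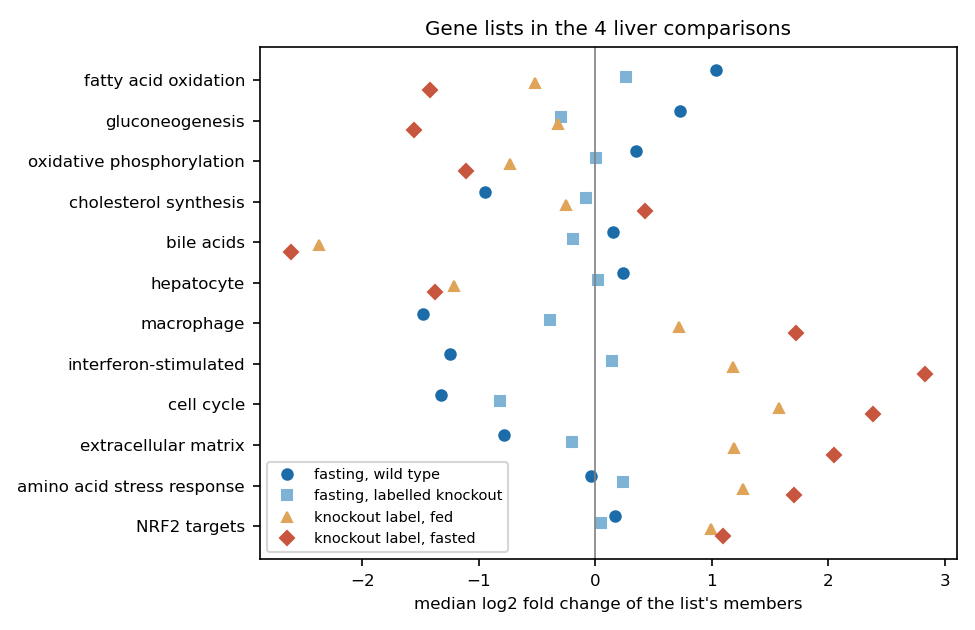
Median log2 fold change (horizontal axis) of the tested members of 12 gene lists (vertical axis) in 4 liver comparisons, 1 symbol per comparison. The fatty acid oxidation list lies at 1.03 on fasting in wild-type livers, at 0.27 on fasting in livers labelled knockout and at −1.42 for the knockout label in fasted liver.

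The interaction asked whether the fasting change itself differed between livers labelled knockout and wild-type livers. It did so past 0.05 for 2873 genes, 1512 with a higher and 1361 with a lower change in livers labelled knockout (edgeR's quasi-likelihood adjusted p). Fatty acid oxidation genes had a lower fasting change in 32 of 56 cases and a higher one in 1 (41 and 3 adjusted over the list alone; median difference −0.79): Cidec by −3.31, Angptl4 by −2.22, the carnitine transferase Cpt1a by −1.64 and the coactivator Ppargc1a by −3.47. Gluconeogenesis and amino acid catabolism genes had a lower change in 21 of 41 cases (28 adjusted over the list alone; median −1.20), among them Lpin2 (−2.54) and Slc7a2 (−2.51). The change of Sqstm1 was lower by −0.79 ± 0.16 (adjusted p = 0.00394), and that of Lamb3 by −4.09 ± 0.43. Sqstm1 already stood at 804 CPM in fed livers labelled knockout, against 609 CPM in fasted wild-type livers. In some of the lists that fell on fasting in wild-type livers, many members had a higher change: 16 of 29 cholesterol synthesis genes, with 1 lower (21 and 1 adjusted over the list alone; median 0.82; Mvd 2.79), 14 of 24 unfolded protein response genes (19; median 0.73; Sdf2l1 1.80), 20 of 43 interferon-stimulated genes (36; median 1.33; Rtp4 1.86) and 15 of 20 macrophage markers (16; median 1.02; Cd68 2.18). The differences for Fgf21 (−2.52, adjusted p = 0.0599), Ppara (−0.59, 0.135), Mat2a (−0.45, 0.132), Atf4 (0.67, 0.059), Nr1d1 (−0.25, 0.88) and Pik3r4 (−0.26, 0.456) were not past 0.05. They passed it for Fgf21 without fed wild-type library c (−3.07), with Ensembl genes alone (−2.54) or by DESeq2 (−2.53), for Mat2a without fasted wild-type library c (−0.55, adjusted p = 0.05), for Ppara without fasted knockout library c (−0.81) and for Atf4 without fasted knockout library b (0.85), without the filter (0.80) or with library sizes alone (0.80). Of 39 named genes past 0.05, 8 of those with the largest changes lost the call without at least 1 library: Oxtr, Dmbt1, Cyp3a44, Cyp3a41b, Mup-ps19, Cyp4a12b, Cyp8b1 and Slc6a16. The 6 lists had camera adjusted p between 1.89e-16 and 1.14e-07 with a preset correlation and between 0.32 and 0.418 with an estimated one. With library sizes alone, 2244 changes were higher and 1014 lower, relative to a median shift of 0.14.

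**Figure D2:**
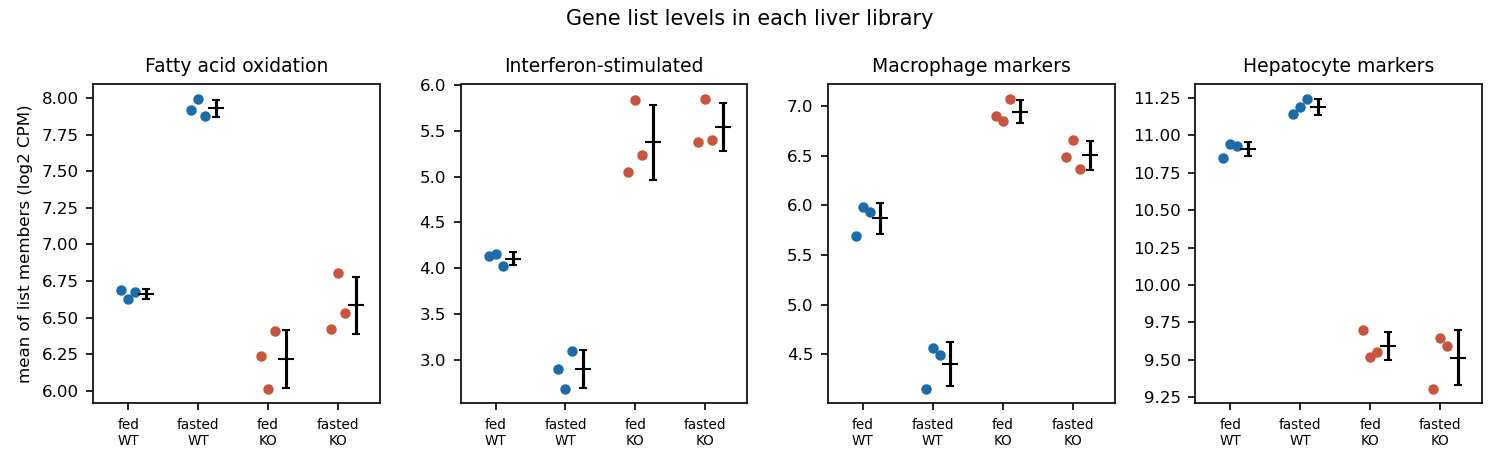
Mean log2 CPM of the members of 4 gene lists (vertical axis) in each of the 12 liver libraries, by group (horizontal axis; KO, labelled knockout), with black bars for the group mean and SD (n = 3). In each of the 3 fasted wild-type libraries fatty acid oxidation genes lie above 7.88, and in the 6 libraries labelled knockout between 6.01 and 6.80.

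In MEFs the columns headed CRE were set against those headed GFP in each of 4 media. Whether the headings match the libraries stayed open, as described below, so media and vectors are those of the headings throughout. In basal and in deprived cells, genes of the amino acid stress response were higher under the CRE heading, 37 and 36 of 40 with 1 lower in each (the same adjusted over the list alone; medians 1.10 and 1.05). Trib3 was higher by 3.50 ± 0.05 (SE of the log2 difference) and 2.79 ± 0.05, the glutathione-degrading enzyme Chac1 by 3.02 and 2.94 and Atf4 (chromosome 15, 80255184 to 80257541, plus strand) by 1.01 and 1.09. Cholesterol synthesis genes were lower in 26 of 28 cases in both media and higher in 0 and 1 (26 lower and 1 higher in both adjusted over the list alone; medians −0.77 and −0.88), as Hmgcs1 (−1.28 and −1.46) and Idi1 (−1.68 and −1.59). Clock genes were higher in 17 of 23 cases in both (17 in both adjusted over the list alone), with Ciart at 2.27 and 1.93 and Nr1d1 at 1.19 and 1.51. Cell cycle genes were lower in 39 and 37 of 49 and higher in 4 in both (39 and 38 lower adjusted over the list alone). Of 45 ribosome biogenesis genes 37 and 43 were higher and 1 lower in each (the same adjusted over the list alone; medians 0.23 and 0.46). Of 38 immediate early genes 21 and 28 were higher and 8 and 7 lower (the same adjusted over the list alone), with Egr1 at 2.86 and 3.56. Mat2a (chromosome 6, 72432799 to 72439558, minus strand) was higher by 1.25 ± 0.15 and 1.42 ± 0.15, and Sqstm1 by 0.75 and 0.53.

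After 1 h and 4 h of replenishment the CRE minus GFP differences had the opposite sign for stress response, immediate early and clock genes. Amino acid stress response genes were lower under the CRE heading in 37 and 33 of 40 cases, with 0 and 2 higher (37 and 34 lower adjusted over the list alone; medians −0.69 and −0.71): Chac1 was at −2.80 and −2.32, Ppp1r15a at −2.59 and −2.50, Herpud1 at −2.48 and −2.45 and Atf4 at −1.54 and −1.38. Immediate early genes were lower in 35 and 36 of 38 and higher in 2 and 1 (the same adjusted over the list alone; medians −1.05 and −1.31), with Myc at −2.41 and −2.75 and Junb at −2.31 and −2.55, and clock genes in 18 and 20 of 23, with 1 higher in each (the same adjusted over the list alone), with Ciart at −1.99 and −1.63. Mat2a was lower by −2.08 and −2.35, Nr1d1 by −0.70 and −1.22 and Sqstm1 by −0.23 and −0.22. Cholesterol synthesis genes were higher in 11 and 19 of 28 and lower in 7 and 1 (the same adjusted over the list alone). Cell cycle genes were higher in 18 and 22 of 49 and lower in 7 and 11 (17 and 23 higher adjusted over the list alone), and ribosome biogenesis genes in 12 and 13 of 45 and lower in 17 and 21 (the same adjusted over the list alone). At 4 h the CRE library numbered 3 stood apart, with 0.654% of counts from mitochondrial genes against 1.64 and 1.65% in the other 2, and Ppara was at 0.30 (adjusted p = 0.0272), a call lost without GFP library 2 (0.30) or 3 (0.18), without CRE library 1 (0.24), without the filter (0.30), in a fit of these libraries alone (0.30) and by DESeq2 on recovered counts (0.54).

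Limma found 8113, 8717, 7658 and 8319 of 13914 genes past an adjusted p of 0.05 between the headings in basal, deprived, 1 h and 4 h cells. Of these 4127, 4457, 3745 and 4283 were higher under CRE. With every library shifted to 1 median, higher and lower calls were 3204 and 5111, 3582 and 5449, 4903 and 3067, and 4924 and 3575 in the 4 media. Camera with a preset correlation gave an adjusted p between 8.23e-25 and 2.32e-13 for the stress response list over the 4 media, between 1.43e-05 and 4.6e-08 for clock genes, between 1.23e-16 and 0.246 for cholesterol synthesis, between 1.03e-22 and 0.00988 for immediate early genes, between 1.13e-12 and 0.175 for the cell cycle and between 3.08e-13 and 0.744 for ribosome biogenesis. With an estimated correlation, the adjusted p of the stress response list was 0.0153, 0.0368, 0.0417 and 0.0838 in the 4 media, of the clock list 0.00369, 0.00623, 0.00158 and 0.00108, of the cholesterol list 0.0035, 0.00404, 0.747 and 0.147, and of the immediate early list 0.416, 0.132, 0.00618 and 0.00305. That adjusted p was 0.23 or more for cell cycle and 0.132 or more for ribosome biogenesis genes in each medium. Ppara differed by −0.21, −0.23 and −0.04 in the first 3 media, not past 0.05 (adjusted p = 0.136, 0.0873 and 0.823). It passed 0.05 in the first 2 with the median shift (−0.27 and −0.31), and in deprived cells without deprived CRE library 1 (−0.30).

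**Figure D3:**
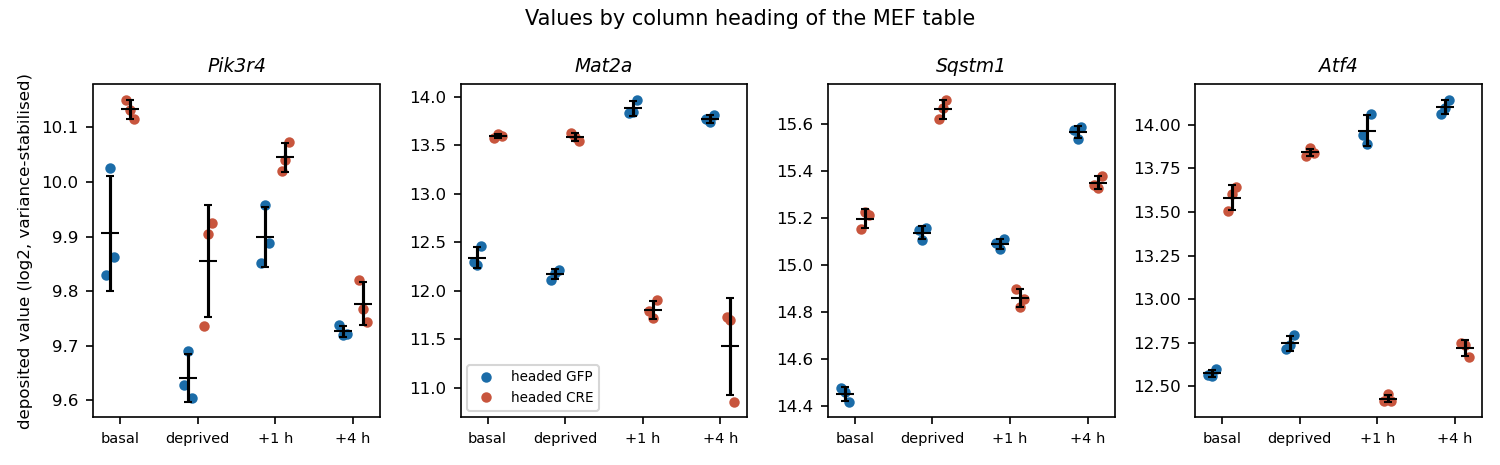
Deposited log2 values (vertical axis) of Pik3r4, Mat2a, Sqstm1 and Atf4 in each of the 24 MEF libraries by medium and heading (horizontal axis; +1 h and +4 h, replenished), with black bars for the mean and SD (n = 3). Atf4 lies higher in columns headed CRE in basal and deprived cells, by 1.01 and 1.09, and lower after replenishment, by −1.54 and −1.38.

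Deprivation of methionine for 4 h was compared with basal medium under each heading. These changes, and those on replenishment below, are effects of methionine only if the headings are right. Interferon-stimulated genes were higher in deprived cells, 40 of 43 under GFP and 38 of 43 under CRE (42 and 41 adjusted over the list alone; medians 1.02 and 0.76): the chemokine Ccl5 rose by 2.67 ± 0.11 and 2.81 ± 0.11, Oas3 by 1.81 and 1.43 and Cxcl10 by 2.01 and 2.54. Autophagy and lysosome genes rose in 46 and 33 of 60 cases and fell in 1 and 2 (47 and 40 rose adjusted over the list alone; medians 0.25 and 0.15), with Sqstm1 up by 0.69 ± 0.03 and 0.47 ± 0.03, Fnip2 by 0.71 and 0.83 and Gla by 0.76 and 0.78. Amino acid stress response genes rose in 30 and 25 of 40, with 0 and 1 falling (31 and 26 rose adjusted over the list alone; medians 0.26 and 0.20), as Chac1 (1.16 and 1.07) and Atf4 (0.17 and 0.26). Cholesterol synthesis genes rose in 24 and 18 of 28, with 0 and 1 falling (25 and 19 rose adjusted over the list alone), as Insig1 (0.82 and 0.77). Mat2a differed by −0.17 and −0.01 (adjusted p = 0.476 and 0.975), past 0.05 under GFP in a fit of these libraries alone. Pik3r4 fell by 0.27 and 0.28. Nr1d1 rose under CRE (0.35) and differed by 0.03 under GFP (adjusted p = 0.815).

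On deprivation the imprinted RNA H19 fell by 1.49 and 1.71 under GFP and CRE and Angptl7 by 0.87 and 1.05. Extracellular matrix genes fell in 19 and 26 of 37 cases and rose in 2 in both (22 and 29 fell adjusted over the list alone), with Sparc at −0.34 and −0.51 and Col5a2 at −0.43 and −0.57. Cell cycle genes fell in 28 and 23 of 49, with 0 and 3 rising (32 and 25 fell adjusted over the list alone), among them Ccnd1 (−0.53 and −0.47). Under GFP 17 of 28 NRF2 targets rose and 3 fell, among them Hmox1 (1.01), and under CRE 8 rose and 5 fell (the same adjusted over the list alone). Under CRE 26 of 38 immediate early genes rose and 1 fell (30 and 1 adjusted over the list alone), among them Junb (0.94), and under GFP 6 rose and 13 fell (7 and 14 adjusted over the list alone). By limma 3290 genes were past 0.05 under GFP, 1397 higher and 1893 lower, and 3963 under CRE, 2091 higher and 1872 lower. By camera with a preset correlation the adjusted p was 0.345 for NRF2 targets under CRE and 0.369 for immediate early genes under GFP and lay between 5.79e-38 and 7.92e-07 for the rest of these lists. With an estimated correlation the adjusted p under GFP and CRE was 0.0317 and 0.0974 for interferon-stimulated, 0.002 and 0.0208 for autophagy, 0.0135 and 0.0974 for stress response, 0.000434 and 0.0183 for cholesterol, 0.206 and 0.0558 for matrix and 0.23 and 0.311 for cell cycle genes. It was 0.000434 and 0.538 for NRF2 targets and 0.742 and 0.0183 for immediate early genes.

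The deprivation change differed between the headings for 665 genes by limma, 450 with a higher and 215 with a lower change under CRE. Immediate early genes had a higher change in 26 of 38 cases (29 adjusted over the list alone; median 0.39), with Junb at 0.82 ± 0.07 and Egr1 at 0.70 ± 0.06. Ribosome biogenesis genes had a higher change in 14 of 45 (31 adjusted over the list alone; median 0.18). NRF2 targets had a lower change in 10 of 28 (13 adjusted over the list alone; median −0.20), with Nqo1 at −0.63 and Hmox1 at −0.59, and 0 of 43 interferon-stimulated genes were past 0.05 (0 adjusted over the list alone; median −0.21). Camera's adjusted p with a preset correlation was 2.88e-28, 6.07e-16, 5.52e-13 and 0.00514. With an estimated correlation the adjusted p was 0.00154, 0.138, 0.000207 and 0.752 for these 4 lists. Sqstm1 had a lower change (−0.22 ± 0.05, adjusted p = 0.00331), while Mat2a (0.16, 0.739), Atf4 (0.09, 0.416), Nr1d1 (0.32, 0.0516) and Pik3r4 (−0.01, 0.951) did not pass. The call for Nr1d1 was made without basal GFP library 1 (0.36) and with the replicate number as a block. The count was 399 without basal GFP library 3, 387 without basal CRE library 1, 360 and 428 without deprived GFP libraries 1 and 2, 424 and 436 without deprived CRE libraries 2 and 3, and 419 without the filter on low values.

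Replenishment of methionine for 1 h was compared with deprivation. Under the GFP heading amino acid stress response genes rose in 38 of 40 cases and fell in 1 (38 and 1 adjusted over the list alone; median 0.98), with Trib3 up by 2.66 and Chac1 by 2.61. Mat2a rose by 1.71 ± 0.15 and Atf4 by 1.22. Immediate early genes rose in 33 of 38 with 1 falling (34 and 1 adjusted over the list alone; median 0.80), with Egr1 up by 3.41 and Myc by 2.58. Under the CRE heading the same lists fell: stress response genes in 33 of 40 (33 adjusted over the list alone; median −0.64), with Chac1 at −3.13, Herpud1 at −2.48, Mat2a at −1.79 ± 0.15 and Atf4 at −1.41. Immediate early genes fell in 28 of 38, with 6 rising (28 and 7 adjusted over the list alone; median −0.92). Interferon-stimulated genes fell under both headings, 39 and 42 of 43, with 0 and 1 rising (the same adjusted over the list alone), and Ccl5 fell by 2.88 under GFP. Cholesterol synthesis genes fell in 26 of 28 cases under GFP (26 adjusted over the list alone; median −1.17) and in 15 with 5 rising under CRE (15 and 5; median −0.19). H19 rose by 2.33 and Angptl7 by 1.66 under CRE. Ppara under GFP differed by −0.21 and was not past 0.05 (adjusted p = 0.128), except with the median shift (−0.29). By limma 8275 genes were past 0.05 under GFP, 4271 higher and 4004 lower, and 8369 under CRE, 4180 higher and 4189 lower, against 3373 and 5229, and 5302 and 3466, with each library shifted to 1 median.

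The 1 h change differed between the headings for 9257 genes, 4658 with a higher and 4599 with a lower change under CRE, or 6107 and 3660 with each library shifted to 1 median, which moved the median of all genes by 0.14. Stress response genes had a lower change in 38 of 40 cases (38 adjusted over the list alone; median −1.79), with Chac1 at −5.74 ± 0.07, Trib3 at −4.55 and Mat2a at −3.50 ± 0.22. Immediate early genes had a lower change in 31 of 38, with 2 higher (31 and 2; median −1.57). Cholesterol synthesis genes had a higher change in 25 of 28 and a lower one in 2 (25 and 2; median 0.87). Atf4 was at −2.63, Nr1d1 at −2.21 and Sqstm1 at −0.76. Pik3r4 rose by 0.26 under GFP and 0.19 under CRE (interaction −0.07, adjusted p = 0.425, and 0.08 with the shift). By camera with a preset correlation the adjusted p of these lists lay between 4.83e-20 and 2.28e-11 under GFP, between 1.52e-16 and 0.0538 under CRE and between 9.33e-20 and 2.48e-10 in the interaction. With an estimated correlation the camera adjusted p of the stress response, immediate early, cholesterol and interferon lists was 0.0221, 0.0148, 0.00121 and 0.285 under GFP and 0.0677, 0.0827, 0.378 and 0.244 under CRE. In the interaction it was 0.022, 0.022 and 0.0174 for the first 3.

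Replenishment for 4 h was compared with deprivation as well. Under GFP stress response genes rose in 38 of 40 cases (38 adjusted over the list alone; median 1.10) and immediate early genes in 34 of 38 (34; median 1.13), with Egr1 up by 4.18 ± 0.04, Chac1 by 3.38, Mat2a by 1.60 and Sqstm1 by 0.43, while 25 of 28 cholesterol synthesis genes fell and 1 rose (25 and 1; median −0.79), with Hmgcs1 at −1.54. Under CRE stress response genes fell in 31 of 40 and rose in 2 (32 and 2; median −0.36), with Herpud1 at −2.17 and Mat2a at −2.16. Immediate early genes fell in 32 of 38 and rose in 3 (33 and 3; median −0.71), with Junb at −2.05. Of 28 cholesterol synthesis genes 24 rose and 2 fell (25 and 2; median 0.28), with Hmgcs1 at 0.88. Of 43 interferon-stimulated genes 14 rose and 7 fell under GFP (12 and 7; median 0.13) and 2 rose and 3 fell under CRE (1 and 2; median −0.10), with camera adjusted p = 0.371 and 0.408, and 0.851 and 0.947 with an estimated correlation. The second count or pair in these parentheses was adjusted over the list alone. Ppara fell under GFP (−0.44, adjusted p = 0.00149), and Pik3r4 differed by 0.09 and −0.08 (adjusted p = 0.143 and 0.21). Without deprived CRE library 1 its value under CRE was −0.14, past 0.05. By limma 9193 genes were past 0.05 under GFP, 4630 higher and 4563 lower, and 7211 under CRE, 3614 higher and 3597 lower. With each library shifted to 1 median these were 3878 and 5465 under GFP and 4618 and 2990 under CRE.

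The 4 h change differed between the headings for 9618 genes, 4883 with a higher and 4735 with a lower change under CRE, or 5888 and 3945 with each library shifted to 1 median, which moved the median of all genes by 0.12. Chac1 was at −5.26 ± 0.07, Egr1 at −5.01 ± 0.06, Myc at −4.73, Mat2a at −3.77 ± 0.22, Atf4 at −2.48, Nr1d1 at −2.74 and Sqstm1 at −0.74, and Hmgcs1 at 2.42 and Nqo1 at 2.45. Stress response genes had a lower change in 38 of 40 cases (38 adjusted over the list alone; median −1.84), immediate early genes in 34 of 38 (34; median −1.91), and cholesterol synthesis genes a higher one in 25 of 28 and a lower one in 2 (25 and 2; median 1.04). By camera with a preset correlation the adjusted p of these lists lay between 2.6e-17 and 3.47e-11 in the interaction, between 1.11e-19 and 6.77e-13 under GFP and between 2e-14 and 2.51e-08 under CRE. With an estimated correlation the camera adjusted p of the stress response, immediate early and cholesterol lists was 0.0291, 0.0116 and 0.0113 in the interaction, 0.0222, 0.0119 and 0.00663 under GFP and 0.0661, 0.0163 and 0.0187 under CRE. Ppara was at 0.53 (adjusted p = 0.00537). Pik3r4 was at −0.16 (adjusted p = 0.0458), a call lost with the median shift (−0.05), without the filter, without the trend and by DESeq2 on recovered counts, and without single libraries: deprived GFP 1 or 3, deprived CRE 2 or 3, GFP 1, 2 or 3 at 4 h and CRE 2 or 3 at 4 h. Without the CRE library at 4 h that stood apart, the counts of genes past 0.05 were 8016 between headings at 4 h, 6797 for the 4 h change under CRE and 9661 for the interaction.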

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

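The tests of the column headings, of the methionine response, of a single library, of hepatocyte share, of library scaling, of spread and of the fed level were chosen after the results were seen, and the splits were planned. A test of the difference between groups singled out 4 results: the fasting change differed between livers labelled knockout and wild-type livers for 2873 genes, and between MEF columns headed CRE and GFP the change differed for 665 genes on deprivation, 9257 after 1 h and 9618 after 4 h of replenishment.

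For these interactions 33 splits of the same libraries were refitted, with the libraries shuffled over all 4 groups. Such splits also mix the effects of fasting or medium and of label or heading. They therefore cannot decide whether chance explains an interaction. In liver 1 of 33 splits, the real one, gave as many genes as 2873 and the highest other gave 0. At 1 h the real split alone gave as many as 9257 (1 of 33, highest other 3466). At 4 h it alone gave as many as 9618 (1 of 33, highest other 5276). For deprivation 7 of 33 splits gave at least 665 genes and the highest other gave 9004. What that split contrasts was not examined. For the 14 comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05. In each, 1 of 10 splits, the real one, gave as many genes. In liver the real values and the highest others were 6282 and 0 on fasting in wild-type, 362 and 3 in livers labelled knockout, 11022 and 0 for the label in fed and 13383 and 0 in fasted livers. Between headings they were 8113 and 0 (basal), 8717 and 0 (deprived), 7658 and 0 (1 h) and 8319 and 1 (4 h). Under GFP and CRE they were 3290 and 0, and 3963 and 0, on deprivation, 8275 and 0, and 8369 and 0, at 1 h, and 9193 and 0, and 7211 and 11, at 4 h.

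The first pattern is the opposite direction of the CRE minus GFP difference before and after replenishment, with correlations across genes of 0.905 between basal and deprived, 0.871 between 1 h and 4 h and −0.547 to −0.611 between the earlier and later media. A single library was not behind it, since the 4 h interaction held 9661 genes without CRE library 3. If the headings were displaced against the libraries, the steps from basal to deprived and from 1 h to 4 h, under GFP and under CRE, which share no library, would all carry 1 common difference. Their 6 correlations across genes, which are not independent replicates, were 0.65 to 0.774, the outcome predicted for displaced headings. With the knockout minus wild-type difference of fed livers, over 11318 genes, the steps had Pearson correlations of 0.078 to 0.114. Those of the CRE minus GFP differences were −0.036 to 0.018. All of these are weak and do not decide whether the headings are right. Pik3r4 also fell in each of these steps (log2 differences −0.172 to −0.278). A common difference does not show which library lies behind which heading. In 1 possible order each of the steps compares both vectors in 1 medium. Mat2a would then be at 12.34 and 12.17 in basal and 13.89 and 13.77 in deprived cells. It would be at 13.6 and 13.59 at 1 h and 11.8 and 11.43 at 4 h. Those pairs are headed GFP basal and deprived, GFP 1 h and 4 h, CRE basal and deprived, and CRE 1 h and 4 h. ND3, given below, sets apart the pair read as deprived. This order was chosen after the values were seen and was not tested. Displaced headings may thus be the source and stay open. A methionine response that depends on Vps15 could be the source only if the headings are right. In that case the amino acid response genes under GFP were predicted to fall at 1 h, but they rose (median 0.978). For these genes the rise argues against that response. The prediction rests on the usual response of cells with Vps15 and holds only if the headings are right.

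The second pattern is the lower level of hepatocyte markers in livers labelled knockout. A smaller share of hepatocytes, with the other cell types in unchanged proportion, would raise their markers alike. Macrophage markers rose more than endothelial ones by 1.96 (SE 0.078) in fasted and 1.11 (SE 0.046) in fed livers, which argues against that form only. A smaller share through a gain of some other cell types is not tested by this gap and stays open. Scaling is not the whole source, since 15 of 18 markers were still lower past 0.05 in fed livers with library sizes alone. Lower expression within hepatocytes after Vps15 loss, or a change in macrophages themselves, may explain the rest and was not tested.

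The third pattern is the smaller number of genes past the threshold on fasting in livers labelled knockout. If a larger spread were the source, the changes would be as large as in wild-type livers. The slope of knockout on wild-type changes over 56 fatty acid oxidation genes was 0.232 (jackknife SE over genes 0.04). In 49 of 56 the signed change was lower in livers labelled knockout. That SE takes genes as units and holds none of the spread between libraries, and the slope was not refitted without single libraries. The interaction above, which takes in that spread, called most of these genes lower by edgeR. Fed livers labelled knockout were not already at the fasted level for this list as a whole (median difference from fed wild-type livers −0.521). Some members, Cidec among them, were nonetheless higher in these fed livers. For 2 lists the fed livers labelled knockout may have been at the fasted level, with medians of −1.316 for unfolded protein response and −0.974 for fatty acid synthesis genes against fasting changes of −0.827 and −0.373. They were not for most of the 13 other lists called lower on fasting, of which 9 had medians at or above 0 and 1, female-biased genes, was as low (−2.70 against −1.65). No single library explained it either, since leaving out 1 library brought the count to at most 1330, against 4681 to 5348 in wild-type livers with 1 left out. The response itself was weaker for fatty acid oxidation genes as a list. A low fed level stays open for the unfolded protein response, fatty acid synthesis and female-biased lists, and a raised one for members such as Cidec. Whether Vps15 loss was the cause was not tested.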

How the results depend on the processing

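Ensembl genes only, library sizes alone and the fits on recovered counts were chosen after the data were seen. Of 249 counts of genes under an alternative, 233 stayed within 1.5 times the original. The others were fasting in livers labelled knockout (362), with 937 by DESeq2, 1456 without the filter, 33 with only the compared groups, 563 with Ensembl genes only and 7 to 1330 leaving out 1 library, and the deprivation interaction (665), with 419 without the filter and 360 to 777 leaving out 1 library. Of 10394 single-gene values 10036 kept direction and side of the threshold, 296 lost the call, 27 gained it and 35 turned direction. Of 302 list tests 220 kept their call, 78 lost it, 72 of them with an estimated correlation, and 4 gained it. With fry, which does not set a list against the other genes, 108 kept their call, 6 lost it and 4 gained it.

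Directions turned without the filter for Pik3r4 on fasting in wild-type livers (−0.022) and between fasted livers (0.04). With library sizes alone they turned for Pik3r4 on fasting in wild-type livers (−0.114) and between fasted livers (0.436), Mat2a (0.304) and Nr1d1 (0.048) between fasted livers and Nr1d1 between fed livers (0.165). With each library shifted to 1 median they turned for Ppara between headings at 1 h (0.031) and at 1 h under CRE (0.054) and for Pik3r4 in the 1 h interaction (0.075). Leaving out 1 library gave Pik3r4 −0.046 to 0.132 on fasting in wild-type livers, −0.179 to 0.036 between fasted livers and −0.073 to 0.046 in the deprivation interaction. It gave Nr1d1 −0.663 to 0.116 between fed livers, −0.549 to 0.203 in the liver interaction and −0.008 to 0.066 on deprivation under GFP, Atf4 −0.122 to 0.239 between fasted livers and Mat2a −0.029 to 0.01 on deprivation under CRE. It gave Ppara −0.047 to 0.324 on fasting in livers labelled knockout, −0.095 to 0.035 in the deprivation interaction, −0.093 to 0.068 between headings at 1 h and −0.071 to 0.09 at 1 h under CRE. The cause was not tested.

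No paired analysis was possible in liver because its columns carry no replicate number. With the MEF replicate number as a block the counts were 8209, 8800, 7751 and 8423 between headings (basal, deprived, 1 h, 4 h), 3438, 4127 and 909 for deprivation (GFP, CRE, interaction), 8355, 8453 and 9331 at 1 h and 9255, 7303 and 9661 at 4 h. In the same order, edgeR on recovered counts called 8188, 8868, 7790, 8453 between headings, 3234, 4055, 665 for deprivation, 8399, 8495, 9428 at 1 h and 9443, 7233, 9838 at 4 h. DESeq2 on them called 7789, 8464, 7254, 8015 between headings, 2941, 3681, 692 for deprivation, 7944, 8038, 9064 at 1 h and 8967, 6844, 9464 at 4 h. The numbers did not pair the samples throughout: of 30 pairs, correlated from −0.148 to 0.23, 4 were over 0.1. In 0 of 10 comparisons was every pair over 0.1. In 17 pairs the correlation was highest with the own number, above an equal share among the 3 numbers, so a weak pairing stays open. At the liver depth the simulated test called 33 of 100 changes of a log2 of 1. Its spread and its number of changed genes were set and not taken from the livers. That share therefore does not give the power in these data.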

Other observations

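Tests of the lists in this part were planned, while the values of single mitochondrial genes and libraries were chosen after they were seen. In livers labelled knockout, 19 of 24 male-biased liver genes were lower in the fed and 22 in the fasted state (19 and 22 adjusted over the list alone; medians −2.29 and −2.83), with Igfals at −3.06 and −2.74 and Igf1 at −1.33 and −1.53 by edgeR. The mean log2 CPM of these 24 genes was 7.02, 5.21 and 5.84 in fed wild-type libraries a, b and c, and that of 19 female-biased genes 4.38, 5.73 and 5.84. Clock genes were lower in 15 and 16 of 23 and higher in 2 in both states (16 and 16 lower adjusted over the list alone; medians −0.96 and −0.99), as Hlf (−2.15 and −1.92). Heat shock genes were lower in 14 and 13 of 17 and higher in 1 and 2 (15 and 14 lower adjusted over the list alone), as Dnaja1 (−1.96 and −1.55). Fetal and regenerating liver genes were higher in 6 and 5 of 9 and lower in 0 and 1 (the same adjusted over the list alone; medians 1.54 and 2.49), with Ly6d at 5.22 and 6.42 and Cpe at 4.30 and 5.76, and Krt8 was higher by 1.58 and 2.81. Camera gave these 4 lists, male-biased, clock, heat shock and fetal, an adjusted p with a preset correlation that lay between 4.79e-08 and 0.0288. With an estimated correlation it lay between 0.217 and 0.384.

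In MEFs the deposited log2 value of the mitochondrial gene ND3 lay between 9.47 and 10.2 in the 6 columns headed GFP after replenishment and between 5.80 and 7.03 in the other 18 columns. With the headings right these 6 columns are replenished cells of 1 vector. In the order of headings described above they are deprived cells of both vectors, and neither reading was tested. ND2 lay between 13.3 and 13.5 in those 6 columns, between 14.1 and 14.5 in 17 of the others and at 13.1 in CRE library 3 at 4 h. CRE library 3 at 4 h of replenishment had 0.654% mitochondrial counts against 1.64 and 1.65% in CRE libraries 1 and 2, and its ND1 value was 13.8 against 15.1 in both.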
